A study of Nothobranchius furzeri with 20 samples.

How the data were processed

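RNA of the skin of male N. furzeri was sequenced in 20 libraries made with a TruSeq kit, per the labels' protocols. Reads were processed with CASAVA 1.8.2, STAR 2.4.1d and featureCounts 1.4.6-p4, per the submitters' processing notes; the genome build, the annotation and the strand setting are not given in the sources used here. The deposited counts are whole reads per gene without normalization, as their values and the counting tool named in the notes show. They are held in 2 tables, 1 with the 15 libraries at 1% and 10% and 1 with the 5 libraries at 0.1%, which list the same 26739 genes in the same order. The authors also deposited RPKM values, reads per unit of gene length and of library size. The ratio of count to RPKM, compared between columns so that gene length drops out, changed from row to row with a period of 35 rows in all 19 pairs of columns tried, which cover each library (SD within rows of the same remainder at most 0.000562 log2, against at least 0.20 over all rows). The values are therefore not divided by 1 total per library, and they were used only in alternatives. Columns were matched to samples by title. Of the columns holding counts 10 match no sample described here, and of those holding RPKM 9 match none; these were not used.

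Genes are listed by identifier alone, and the files do not pair identifiers with names. Of the 26739 identifiers 0 matched the table of gene names given for assembly NfurGRZ-RIMD1, so no gene is named. The 27 gene lists fixed before the data were examined (respiratory chain subunits, stress and metabolic pathways, and markers of cell types that a piece of fish skin can hold) could not be tested, nor could the fits that needed the muscle list. The rule for named genes took, among genes with an adjusted p under 0.05, a mean log2 CPM of at least 1 and no overlap between both groups in CPM, those with the largest increases and decreases. It also asked for a symbol, which was dropped here, and only the largest increase and decrease of the 2 comparisons made within the first table are given, 4 identifiers in all.

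Samples were grouped by the dose and age in the labels. Replicate numbers only name libraries, and nothing pairs libraries across groups. The labels do not say in so many words that each library is a different fish, so p-values measure the spread between these libraries. No 2 libraries of a group agreed within sampling noise: the smallest chi-square per degree of freedom between replicates was 34.4. Tests were run in R 4.3.3 with edgeR 4.0.16, two-sided: TMM normalization, filterByExpr, glmQLFit and glmQLFTest with 1 mean per group, and Benjamini-Hochberg adjustment within a comparison. The 2 comparisons within the first table used its 15 libraries, and those with 0.1% used all 20. SEs of log2 changes were derived from the fitted change and its F statistic. CPM values in the text use the TMM factors of all 20 libraries, and log2 CPM values a prior count of 2. Levels at 0.1% are set across both tables, and a difference between the tables would appear as a dose effect.

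The correlation of the age and dose effects used differences of mean log2 CPM. Overlaps of comparisons that share the 1% libraries were set beside 10 simulations of unchanged groups and beside all 20 divisions of these libraries into 2 and 3. Counts of unchanged groups were drawn per gene from 1 mean and 1 spread, estimated over all 20 libraries. Fits were tested on simulated counts with 200 changed genes. For 10% against 1% (18473 genes) edgeR recovered 6 of 67 genes changed 1.5-fold, 34 of 67 changed 2-fold and 58 of 66 changed 4-fold, with 6 false calls among 104. DESeq2 made 36 false calls among 154 there. For 10% against 0.1% (18808 genes) edgeR made 2 false calls among 80 and DESeq2 27 among 128.

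Alternatives fixed before the data were examined were RLE and upper quartile normalization, no filter beyond 1 read, a filter of at least 50 reads in 5 libraries, the Wald test of DESeq2 1.42.0, fits of the 10 libraries of each pair of groups, limma 3.58.1 on log2 RPKM with a pseudocount of 1 or 0.1, and leaving out each library. Fits without the libraries that stand apart, with all 20 libraries, and with a length trend removed were added after the data were seen. Gene length there was a stand-in, the median over libraries of the ratio of count to RPKM. Totals between 21770720 and 29017737 reads leave counting error small beside the spread between libraries for all but genes with few reads. Genes that overlap or are near copies of each other share reads in ways the counts do not resolve.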

Results

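Skin of the turquoise killifish Nothobranchius furzeri, a short-lived annual fish, was profiled by RNA sequencing in males of the strain MZM-04/10p given rotenone, an inhibitor of complex I of the mitochondrial respiratory chain. The dose is stated as a percentage of LC50, the median lethal concentration. The 20 libraries fall into 4 groups of 5: 0.1%, 1% and 10% of LC50 at 9 weeks of age, and 1% at 27 weeks. The labels list no untreated fish, so each comparison is between doses or between ages under rotenone. Library totals ran from 21770720 to 29017737 reads counted on genes, a ratio of 1.33, and 20868 to 21932 of the 26739 genes had at least 1 read in a library.

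Libraries of the 27-week group were the most alike, with a mean pairwise Spearman correlation across genes of 0.978, against 0.958 at 9 weeks and 1%, 0.943 at 10% and 0.920 at 0.1%. On the first principal component, which held 26.0% of the variance, replicates 1 and 4 of the 0.1% group lay at 135.6 and 110.9, and the next library, replicate 3 of the 10% group, lay at 34.3. Both libraries shared 331 genes that were at least 8-fold above each of the other 3 libraries at 0.1%, and 0 genes were at least 8-fold below. These genes took 1.95% and 1.32% of the reads of replicates 1 and 4, and 0.261% of those of replicate 3 at 10%. The second component, with 15.3% of the variance, set replicates 1 and 2 of the 10% group (92.6 and 78.7) apart from the remaining libraries. The 10 most abundant genes took 21.3% ± 1.60 (SD, n = 5) of reads at 10%, 17.48% ± 5.11 at 1% and 17.9% ± 4.90 at 0.1%, and 13.9% ± 0.419 at 27 weeks. The difference between 10% and 1% of 3.85 points was not beyond the spread between libraries (two-sided exact permutation p = 0.159, Benjamini-Hochberg adjusted over the 4 comparisons 0.254).

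**Figure D1:**
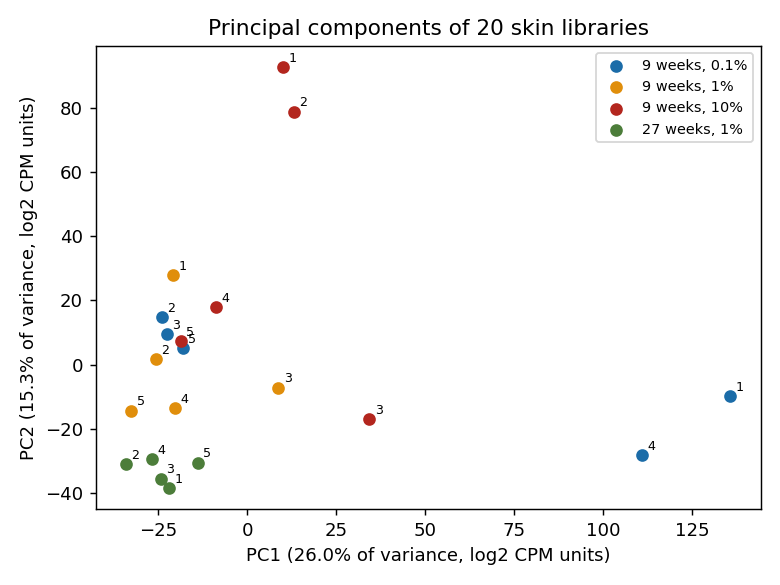
Each point is 1 of the 20 libraries on the first (horizontal) and second (vertical) principal component of log2 CPM, coloured by group and numbered by replicate. Replicates 1 and 4 at 0.1% lie at 135.6 and 110.9 on the first component, and replicates 1 and 2 at 10% lie at 92.6 and 78.7 on the second.

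The comparison of 10% with 1% at 9 weeks asks which transcripts differ across the upper dose step. Of 18473 genes tested, 780 were higher and 902 lower at 10% (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The genes that rose had a median fold change of 1.82, with 328 over 2-fold, and those that fell had a median of 1.57, with 142 over 2-fold. Together the risers took 6.09% ± 1.66 (SD, n = 5) of reads at 10% against 3.86% ± 0.584 at 1%, and the genes that fell took 1.997% ± 0.202 against 3.70% ± 0.489. Among the 131 genes tested with a mean log2 CPM of at least 10, 11 were called. The 2 groups did not overlap for 879 of the called genes and for 6.24% of all genes tested, where chance gives 0.794%. Of the higher genes, 390 had a mean log2 CPM of at least 1 and no overlap between the groups. The largest increase among them was that of Nfu_g_1_000910, from 1.36 ± 0.605 CPM at 1% to 80.6 ± 155 CPM at 10% (SD, n = 5, log2 change 5.88, SE 1.18, edgeR adjusted p = 0.0117). Its mean at 10% rests on replicate 1, at 358 CPM, the other 4 libraries lying between 3.94 and 18.2 CPM. Without that library the log2 change was 3.03 with an edgeR adjusted p of 0.0084. Of the lower genes, 453 met the same conditions. The largest decrease among them was that of Nfu_g_1_013664, from 63.4 ± 25.1 CPM to 18.2 ± 3.16 CPM (log2 change -1.80, SE 0.24, edgeR adjusted p = 0.00478). That all 5 libraries at 10% were below all 5 at 1% was a condition of its choice. The number of called genes depended on single libraries: it was 866, 642, 690 and 1066 without replicates 1, 2, 4 and 5 at 1%, and 1062, 1005 and 967 without replicates 1, 2 and 4 at 10%. The excess of lower genes turned without replicate 2 (546 higher, 459 lower) or replicate 4 (497 and 470) at 10%. A fit on these 10 libraries alone called 468 genes, DESeq2 called 2565, and limma on the deposited RPKM called 171 higher and 603 lower (pseudocount 1).

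The comparison of 27 with 9 weeks was made at 1% of LC50, the dose given at both ages, and asks which transcripts differ with age under rotenone. At 27 weeks 385 genes were higher and 444 lower, of 18473 tested (edgeR, adjusted p under 0.05). The median fold change was 1.56 among genes that rose and 1.87 among those that fell, and 74 and 200 of them exceeded 2-fold. The risers took 3.07% ± 0.110 (SD, n = 5) of reads at 27 weeks and 2.003% ± 0.239 at 9 weeks, while genes that fell took 1.52% ± 0.178 and 3.08% ± 0.532. Groups did not overlap for 526 of the called genes and 5.95% of all genes tested, against 0.794% by chance. Of the called genes, 218 lower and 258 higher had a mean log2 CPM of at least 1 and no overlap between the groups. The largest decrease among them was that of Nfu_g_1_003310, from 25.8 ± 22.505 CPM at 9 weeks to 1.07 ± 0.429 CPM at 27 weeks (log2 change -4.59, SE 0.67, edgeR adjusted p = 0.0134). The same gene was at 16.2 ± 16.6 CPM at 0.1% and 19.8 ± 9.83 CPM at 10%, so the older fish lay below every younger group. The largest increase among the 258 was that of Nfu_g_1_022296, from 20.2 ± 4.96 CPM to 107 ± 97.6 CPM (log2 change 2.41, SE 0.48, edgeR adjusted p = 0.0241), with replicate 3 at 27 weeks at 272 CPM. Without that library the log2 change was 1.71 with an edgeR adjusted p of 0.0364. At 9 weeks Nfu_g_1_022296 was also at 77.9 ± 31.5 CPM at 0.1% and 50.7 ± 17.475 CPM at 10%. Libraries of both doses overlapped those at 27 weeks. Among the younger groups, only that at 1% had this gene below every library at 27 weeks. Its call was lost without replicate 2 at 9 weeks (edgeR adjusted p = 0.0722) and without replicates 2 and 5 at 27 weeks (0.0529 and 0.0564), and in the fit of these 10 libraries alone (0.0552). The number of called genes moved by more than 1.5 times with each of the 10 libraries: it was 325, 17, 1754, 433 and 481 without replicates 1 to 5 at 9 weeks, and 94, 61, 255, 458 and 52 without replicates 1 to 5 at 27 weeks. It was 103 in the fit of the 10 libraries alone and 1995 with DESeq2. The excess of lower genes turned with all 20 libraries in the fit (240 higher, 183 lower), without replicates 2 or 3 at 9 weeks (10 and 7, 885 and 869) or replicates 2, 4 or 5 at 27 weeks (39 and 22, 234 and 224, 27 and 25), and with limma on the deposited RPKM (981 and 120 with a pseudocount of 1, 906 and 134 with 0.1). With RPKM the median log2 change over all genes was itself shifted, at 0.129 and 0.185 against -0.021 in the counts.

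The comparison of 1% with 0.1% at 9 weeks covers the lower dose step. The 0.1% libraries come from a count table of their own, so that dose and table coincide in this comparison and the next. Of 18808 genes tested, 1585 were higher and 1888 lower at 1% (edgeR, adjusted p under 0.05). Genes that rose changed by a median of 1.60-fold and genes that fell by 1.97-fold, and 310 and 925 of them exceeded 2-fold. The risers took 6.06% ± 0.540 (SD, n = 5) of reads at 1% and 3.64% ± 0.438 at 0.1%, and the genes that fell took 3.92% ± 0.793 and 7.65% ± 2.79. Both groups were free of overlap for 1475 called genes and for 8.65% of genes tested, against 0.794% by chance. Of the genes described for the other comparisons, Nfu_g_1_013664 was higher at 1% than at 0.1% (28.4 ± 9.50 CPM; log2 change 1.16, SE 0.25, edgeR adjusted p = 0.00478) and Nfu_g_1_022296 was lower (77.9 ± 31.5 CPM at 0.1%; log2 change -1.95, SE 0.46, edgeR adjusted p = 0.0072). Without replicates 1 and 4 at 0.1%, the libraries apart on the first component, 1506 genes were higher and 871 lower, and 1734 of these were also called with all libraries. The count fell to 2300 without replicate 4 alone. The excess of lower genes turned with upper quartile normalization of all 20 libraries (1868 higher, 1609 lower) and, separately, in a fit of the 10 libraries of these groups alone (663 and 496, 1159 in all). It also turned without replicates 1, 2 or 5 at 1% (1214 and 1207, 1350 and 1089, 1287 and 1225) or replicates 1 or 4 at 0.1% (1540 and 1096, 1241 and 1059).

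Between 10% and 0.1% at 9 weeks, the widest dose step, 0 of 18808 genes passed an adjusted p of 0.05 with edgeR, while 3855 had an unadjusted p under 0.05, where 940 would by chance. DESeq2 called 912 genes, 403 higher and 509 lower. The groups did not overlap for 519 genes, 2.76% of those tested, against 0.794% by chance. Nfu_g_1_000910, at 3.69 ± 2.27 CPM (SD, n = 5) at 0.1%, had the log2 difference 4.44 (SE 1.01, edgeR adjusted p = 0.130), and Nfu_g_1_013664 had -0.64 (SE 0.25, edgeR adjusted p = 0.173). Leaving out both libraries that stand apart at 0.1% gave 0 genes as well. On simulated counts the same fit found 26 of 67 genes changed 2-fold and 46 of 66 changed 4-fold. They had the depth of the libraries and 1 spread per gene estimated over all 20, with genes drawn independently. Libraries at 10% and 0.1% were less alike (mean Spearman correlation 0.943 and 0.920) than those at 27 weeks (0.978). The shares found may therefore be too high for this comparison.

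**Figure D2:**
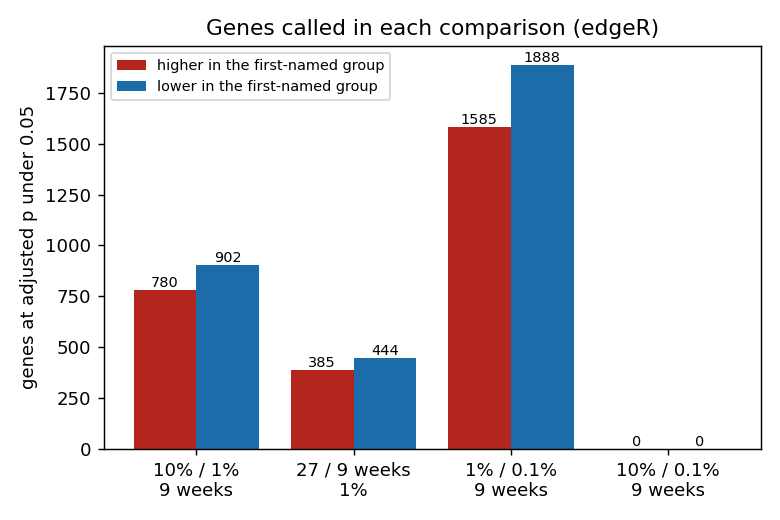
Bars give the number of genes (vertical axis) at an edgeR adjusted p under 0.05 in each of the 4 comparisons (horizontal axis), higher (red) or lower (blue) in the group named first. The counts are 780 and 902, 385 and 444, 1585 and 1888, and 0 and 0.

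Of 18472 genes tested at both steps, 637 were higher at 1% than at both 0.1% and 10%, and 460 were lower at 1% than at both. No gene rose at both steps or fell at both (edgeR; 0 and 0 genes). Both steps share the 1% libraries, which pushes their changes in opposite directions. Independent lists of these sizes, a value that takes no account of the shared libraries, would share 77.4 genes highest and 77.1 lowest at 1%, and 66.9 that rose and 89.2 that fell at both steps. Unchanged simulated groups shared 0 genes, but had 0 called genes at either step, so that this says nothing about the overlap. With the 1% libraries divided so that no library entered both steps, the mean over 20 divisions was 100 genes (0 to 261) highest at 1% and 51.9 (0 to 141) lowest at 1%, with 0.3 (0 to 3) that rose and 0.6 (0 to 8) that fell at both steps. The covariance across genes of the log2 changes at both steps was -0.184, against -0.0768 in unchanged groups, a difference of -0.107. With divided libraries it was -0.120. The unchanged groups had 1 spread per gene estimated over all 20 libraries. Their shared noise need not be that of the 1% libraries, so the difference is uncertain.

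Whether the higher dose and age moved the same genes was asked in 2 ways. The age effect at 1% and the effect of 10% over 0.1%, which share no library, had a Pearson r of -0.13 across 18808 genes (permutation p = 0.44 over 100 labellings of the 10 dose libraries, two-sided) and a Spearman rho of -0.14 (permutation p = 0.37). Genes are not independent replicates, so the library labels were permuted, and the correlation was not beyond what other labellings gave. The age effect and the effect of 10% over 1% share the 1% libraries. There 113 genes were higher in both and 119 lower in both, where independent lists of these sizes would share 16.3 and 21.7, a value that takes no account of the shared libraries. Unchanged simulated groups shared 0, but had a mean of 0 and 0.1 called genes, too few to share any. With divided 1% libraries the mean overlaps were 1.65 (0 to 16) and 0.7 (0 to 9) genes. These fits hold only 2 or 3 libraries at 1% per effect, so the fall can also come from fewer calls, which were not counted. The covariance of these effects was 0.0802 against 0.0761 in unchanged groups, a difference of 0.0041, and 0.0168 with divided libraries. The spread simulated was again estimated over all 20 libraries, so the difference of 0.0041 is uncertain. The r of both effects was 0.31, against 0.50 in unchanged groups. Noise of the shared 1% libraries alone gives about 0.50, and real but unrelated effects would lower it. The gap therefore says nothing about whether age and dose moved the same genes. The mean r with divided libraries was 0.06, and it ran from -0.09 to 0.27.

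**Figure D3:**
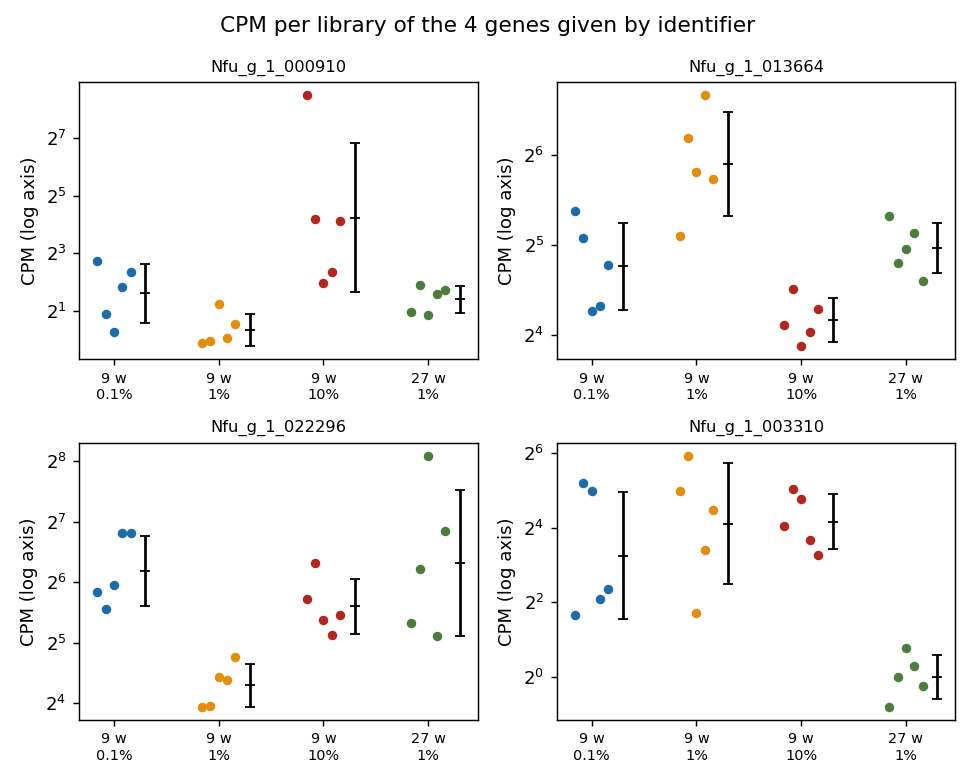
CPM per library (vertical, logarithmic axis) for the 4 genes given by identifier, in each group (horizontal axis, age in weeks and dose in percent of LC50); black marks are the mean and SD of log2 CPM over 5 libraries. Nfu_g_1_003310 lies between 0.571 and 1.71 CPM in all 5 libraries at 27 weeks, and Nfu_g_1_000910 reaches 358 CPM in 1 library at 10%.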

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

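The tests on the 2 libraries apart at 0.1%, on the table of the 0.1% libraries and on the RPKM divisors were chosen after these results were seen. The length test was also added after the data were seen, though what it would show was written down before its own result, as for the splits of the libraries.

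In 0.1% replicate 3 the most abundant gene took 4.98% of reads, against 2.68% to 3.005% in the other 4 libraries, a gap larger than the limit of Dixon's test for 5 samples. It was the only 1 of 40 groups of values examined to pass this limit, and chance passes about 1 in 20.

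Replicates 1 and 4 at 0.1% stand apart from all other libraries on the first principal component, and 331 genes were at least 8-fold higher in both than in each of the other 3 libraries at 0.1%. Depth is excluded, since both totals, the lower being 21977356 reads, lie inside the range of the other 18 libraries, and so are a few genes taking most of the counts, since the 10 most abundant took at most 13.99% there against 17.9% to 25.3% in the other 3. RNA of another tissue or cell type in the piece of skin may be a source: in replicate 3 at 10%, which took no part in choosing the genes, 303 of the 331 genes exceeded the other 4 libraries, and their excess in CPM ranked like that of both libraries (rho across genes at least 0.925), at a median of 14.54% and 22.4% of it. Replicate 3 at 1% (median log2 excess 1.04, rho 0.651 and 0.674) and replicate 5 at 27 weeks (0.54, rho 0.533 and 0.527) also showed it, more weakly, and in the other 12 libraries outside 0.1% rho ran from -0.398 to 0.0448. Replicate 3 at 10% lay next to the libraries apart on the first component, so its high level of these genes is no independent test. A programme switched on in cells of the skin of single fish would give the same ranking and stays open, and no tissue can be named without gene names.

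The 1% libraries at 9 weeks differ from both other doses, while 10% and 0.1% differ in 0 genes with edgeR (3855 at an unadjusted p under 0.05, 912 with DESeq2). Of 100 splits of the 10 libraries, 1, the real one, reached 1682 genes for 10% against 1% (highest other 679). The same held for age (829, highest other 17) and for 1% against 0.1% (3473, highest other 1271). This argues against chance but does not exclude it: 100 splits were run for each, and the 3 comparisons share the 1% libraries at 9 weeks. For 10% against 0.1% the real count of 0 is reached by all 100 splits by construction, so the splits say nothing about chance there. The highest gave 1363 genes, with replicates 1, 2 and 3 at 10% beside replicates 1 and 4 at 0.1%. Splits with 1339, 1273 and 1075 genes also kept replicate 3 at 10% on the side of replicates 1 and 4 at 0.1%. These libraries are the highest in the genes that set replicates 1 and 4 apart, and no other structure of the samples was tested. On 500 genes chosen with other 1% libraries, the effect of 10% over 0.1% was 0.317 of that of 1% over 0.1% (0.262 to 0.401 over 10 splits). This argues against a difference between the tables as the only source. A table difference beside a dose effect cannot be told apart, since the 0.1% libraries have a table of their own. Without the libraries apart 2377 genes were called for 1% against 0.1%, 1734 of them among the 3473 called with all libraries. The genes lower at 1% went from 1888 to 871, so part of the list depends on the libraries apart. With a length trend removed, 1676 genes were called for 10% against 1%, which argues against transcript length as the source. Length was a stand-in from the ratio of count to RPKM, so this holds only as far as that ratio tracks length. A response to 1% that is absent at 10% may lie behind the difference of the 9-week 1% libraries from both other doses. So may a difference in the keeping or collection of the 9-week 1% fish, of which the labels hold no record. Neither was tested. The 27-week fish also received 1%, yet 829 genes differed between them and the 9-week 1% fish. Of genes called both for 10% over 1% and for age, 113 were higher and 119 lower in both, against 1 and 0 in opposite directions. The shared 1% libraries push these changes the same way, so this overlap does not decide between the sources.

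The deposited RPKM values may have been divided by library totals recycled down the rows. Between columns of 2 libraries the ratio of count to RPKM had an SD of 0.20 (log2) over all rows and of 0.000458 within rows of the same remainder at a period of 35, and the lowest SD at any period up to 200 that is no multiple of 35 was 0.19. No biological explanation was tested for this pattern.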

How the results depend on the processing

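The fits with all 20 libraries, without the libraries apart and with the length trend removed were chosen after the data were seen. For 10% against 1% (1682 genes), DESeq2 called 2565, the 10 libraries alone 468, limma on RPKM 774 (171 higher, 603 lower) and 803 (187 and 616) with pseudocounts of 1 and 0.1, and fits without 1 library 642 to 2421. In each comparison with called genes, the excess of lower genes turned in some fits without 1 library. For age (829 genes), the values were 1995 with DESeq2, 103 with the 10 libraries alone, 423 with all 20 (240 higher, 183 lower), and 17 to 1754 without 1 library. Limma on RPKM called 1101 (981 higher, 120 lower) and 1040 (906 and 134), against 385 and 444 in the counts. The median log2 change over all genes was 0.129 and 0.185 with RPKM, against -0.021 in the counts. The RPKM values, which were not scaled by TMM, were thus shifted upward as a whole at 27 weeks. For 1% against 0.1% (3473 genes), the 10 libraries alone gave 1159, or 1274 among genes of mean log2 CPM at least 1, fits without 1 library 2300 to 3905, and the fit without the libraries apart and replicate 3 at 10% gave 2315 (1504 higher, 811 lower). For 10% against 0.1% (0 genes), DESeq2 called 912 and fits without 1 library 0 to 1, the 1 gene without replicate 2 at 0.1%. Fits of 10 libraries have fewer samples to estimate the spread, but whether this lowered their counts was not tested. Nor was the cause tested for the other fits. Normalization by RLE or upper quartile and both filters kept all 4 counts within 1.5 times, but upper quartile turned the balance of 1% against 0.1% (1868 higher, 1609 lower). The length trend, up to 0.56 log2 in a library, left 1676, 874, 3466 and 0 genes. The correlation of the age and dose effects stayed negative and short of the threshold in all 24 alternatives, r from -0.22 to -0.04. No direction of a named gene reversed. Nfu_g_1_000910 (log2 3.03 to 6.19) lost its call in the 10-library fit (edgeR adjusted p = 0.0517, the highest of its alternatives) and has no adjusted p in DESeq2; Nfu_g_1_022296 lost its call in 4 of 20 alternatives, and the other 2 genes in 0. The muscle covariate, the gene lists and the correlation without the muscle list were not run, since no identifier has a name. No paired analysis was possible because the columns carry no shared replicate numbers. Depth limits mainly genes with few reads.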
